A study of Mus musculus with 20 samples.

How the data were processed

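RNA of mouse CD4 T cells was sequenced in 20 libraries. Per the labels' protocols, transfer-part libraries were made with a stranded mRNA kit after sorting; the kit of the culture part is not given in the sources used here. The authors deposited 1 table of read counts per gene and library, whole numbers that were not normalised. Per the submitters' processing notes, the tools were STAR 2.5.3, SAMtools 0.1.18, HTSeq 0.7.2, DESeq2 1.18.1 and R 3.4.3 with mouse build GRCm38 (mm10). The notes used here give no strand setting or annotation release, so counts of overlapping and antisense genes are uncertain, as are those of genes with near-identical copies. HTSeq counts unique alignments, which lowers genes with pseudogene copies.

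Each table held 39179 gene IDs and 5 summary lines. The summary lines were left out of library sizes and tests. Reads in no gene made up between 18.1% and 30.8% of unique reads in the transfer part and between 21.1% and 31.9% in the culture part, and ambiguous reads between 0.526% and 0.844%. Symbols and positions came from the GENCODE M21 annotation of GRCm38, which held 37693 of the IDs. The 1486 others kept their counts without a name.

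Groups were taken from sample titles in the transfer part and from source names in the culture part. The transfer part had 4 groups (before transfer 2 libraries per genotype, colon 3 per genotype) and the culture part 5 groups of 2. Before transfer, the culture held TGF-beta at 2.5 ng/ml and hyper-IL-6 at 20 ng/ml and lasted 6 days; 200000 cells of each genotype were transferred. In the culture part, TGF-beta was at 2.5 ng/ml, IL-6 at 20 ng/ml and hyper-IL-6 at 63 ng/ml for 6 days, and the labels give a 4 h stimulation with PMA and ionomycin for all 10 libraries, naive ones included.

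Each part was fitted on its own with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood F test, TMM scaling, a filter by expression per group, and group as the only factor, so that all groups of a part share 1 estimate of the spread. This left 14225 genes in the transfer part and 14926 in the culture part, with a common biological coefficient of variation of 0.309 and 0.124. Genes with a Benjamini-Hochberg adjusted p under 0.05 passed. There were 12 comparisons. Gene lists, 28 in number, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, adjusted over the lists of a comparison), then with an estimated correlation and with fry, which asks whether a list moves on balance in one direction. With an estimated correlation, camera rests on the residual degrees of freedom, 6 in the transfer part and 5 in the culture part. It then has little power, and a list that does not pass may still have moved. Lists with 2 tested members were not given a set test.

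Genes named in the text follow a rule fixed before the data were examined. It takes 17 genes of the IL-6 and Th17 field in every comparison, the 6 largest changes in each direction among genes that passed with mean log2 CPM of at least 2 and groups that did not overlap, and up to 4 members of each list. Predicted genes, RIKEN clones and names of immunoglobulin or T cell receptor segments were left out of the largest changes. Lists, comparisons and most alternatives were also fixed before the data were examined. Genes outside the rule are said to have been named after their values were seen. Fitted folds of genes with no count in a group are no bounds, so only levels are printed for them.

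Alternatives were RLE size factors, no filter on low counts, a stricter filter, a 2-fold minimum, DESeq2 1.42.0, the compared groups only, the replicate number as a block, an experiment term and each library left out. Added after seeing the data were DESeq2 on the compared groups only, the compared groups only with the block, the 3 cultured groups only, fits without the doubted libraries of the transfer part (wild-type library 1 before transfer and wild-type colon library 2), and camera with a block and an estimated correlation. In the transfer part the labels tie number 0 to one experiment and numbers 1 and 2 to another, and both genotypes were transferred together. Which colon libraries of numbers 1 and 2 shared hosts was inferred from the numbers. Within a stage, deviations of same-numbered libraries correlated across genes at 0.58, 0.237 and 0.183 after transfer and at 0.43 before. The numbers were taken to pair the libraries within a stage. Only same-numbered libraries were correlated, so a shared experiment could give these values too. That colon libraries 1 and 2 pair by number is therefore an assumption. No 2 libraries of a group agreed within sampling noise, as the mean chi-square per gene was between 7.2 and 262.

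The tests were tested on simulated counts drawn from the real means and library sizes, with 100 genes changed at each of 2 sizes. In the colon genotype comparison (14225 genes) edgeR recovered 25% of 2-fold and 77% of 4-fold changes with 7 unchanged genes called, and DESeq2 called 125 changed and 39 unchanged genes of 13950. In the culture comparison of hyper-IL-6 and IL-6 (14926 genes) edgeR recovered 78% of 2-fold changes with 12 unchanged genes called. Recovery of 2-fold changes was between 2% and 25% in the comparisons of the transfer part and between 52% and 79% in those of the culture part. Depths of the parts overlapped, and whether depth or spread sets this difference was not tested.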

Results

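The series measured mRNA of mouse CD4 T cells of the Th17 lineage, the helper T cells that make IL-17, with and without Il6ra, the gene of the IL-6 receptor alpha chain. It held 20 libraries in 2 parts that were never fitted together. In the transfer part, IL-17F reporter T cells of wild-type (CD45.1) and Il6ra-deficient (CD45.2) mice were cultured as Th17 cells with hyper-IL-6, a fusion of IL-6 with its soluble receptor that acts on cells lacking their own receptor. Reporter-positive cells were sequenced before transfer (2 libraries per genotype). The same kinds of cells were also placed together into Rag1-deficient mice, which have no T or B cells of their own, and CD4 T cells were sorted from the colon 4 weeks later by CD45 allele (3 pooled libraries per genotype). In the culture part, naive CD4 T cells of both genotypes were compared with wild-type cells cultured with IL-6, wild-type cells cultured with hyper-IL-6 and Il6ra-deficient cells cultured with hyper-IL-6 (2 libraries each). Gene counts per library summed to between 12718633 and 23745060 in the transfer part and between 20160774 and 46848016 in the culture part. Levels are TMM-normalised CPM (edgeR counts scaled by library size) as mean ± SD, and log2 fold changes are given ± SE. Except where cells were pooled from several mice, the labels do not say whether libraries came from separate animals, so p-values measure the spread between these libraries.

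Il6ra itself, which lies on chromosome 3 from 89864059 to 89913196 (GRCm38), was read in every library, since the labels do not give the deleted part and counts over the whole gene need not fall in a deletion. Before transfer its CPM was 84.2 and 72.8 in the wild-type libraries and 80.6 and 123 in the Il6ra-deficient ones. In the colon it was 10.7, 4.32 and 5.40 in wild-type and 4.85, 3.46 and 2.53 in Il6ra-deficient libraries. In naive cells it was 270 and 422 in wild type and 199 and 213 in deficient cells, and in culture 37.2 and 30.6 with IL-6, 39.8 and 39.2 in wild type with hyper-IL-6, and 32.3 and 31.8 in the libraries labelled Il6ra-deficient. The counts of this gene therefore do not check the genotype labels.

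After transfer, colon CD4 T cells without Il6ra had lower Th17 programme genes and higher Th1 genes and CD8, NK and gamma-delta T markers as sets than the wild-type cells of the same hosts, by camera with a preset correlation, while 0 lists passed with an estimated one. Of the 18 measured Th17 programme genes, 11 fell when p was adjusted over the list alone, and 0 passed over all genes. Il22, the gene of an epithelial barrier cytokine, was at 13.3 ± 3.59 CPM against 72.6 ± 17.3 (log2 fold change -2.45 ± 0.41, adjusted p = 0.0509) and the IL-1 receptor gene Il1r1 at 62.2 ± 12.6 against 320 ± 63.0 (-2.36 ± 0.42, adjusted p = 0.0767), each with n = 3 in edgeR's quasi-likelihood test. The cytokine genes Il17a (12.3 ± 8.24 against 71.8 ± 41.6 CPM) and Il17f (1.48 ± 0.93 against 10.6 ± 4.19) and the IL-23 receptor gene Il23r (4.81 ± 2.42 against 18.9 ± 6.99) had log2 fold changes of -2.53, -2.78 and -1.96 and did not pass over all genes either. The labels place number 0 in one experiment and numbers 1 and 2 in another, and pairing by number within an experiment was inferred. With the replicate number as a block, 8 Th17 programme genes fell over all genes. Over the list alone, 13 fell and 1 rose. Those that fell over all genes with the block included Il17a (-2.65 ± 0.32, adjusted p = 0.0116), Il17f (-2.89 ± 0.22, adjusted p = 0.0024), Il22 (-2.45 ± 0.29, adjusted p = 0.0116), Il23r (-2.02 ± 0.30, adjusted p = 0.0286) and Il1r1 (-2.36 ± 0.23, adjusted p = 0.0058). As a set, the Th17 programme was lower than other genes (camera adjusted p = 1.99e-12). With an estimated correlation the adjusted p was 0.092, and with fry it was 0.06, so the list passed neither.

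Over all 14225 genes tested, 22 passed, 9 higher and 13 lower in Il6ra-deficient colon cells. Under the naming rule, which leaves out predicted genes, the largest rise was in Il1rl1, the receptor of IL-33 (158 ± 45.5 against 8.84 ± 4.26 CPM, log2 fold change 4.16 ± 0.43, edgeR adjusted p = 0.00851). Next came Nav1 (3.72 ± 0.48, adjusted p = 0.0168), Eps8l1 (2.95 ± 0.29, adjusted p = 0.00851), Camk2b (2.88 ± 0.41, adjusted p = 0.025), Il12rb2, the signalling chain of the IL-12 receptor (215 ± 23.4 against 32.1 ± 6.52 CPM, 2.74 ± 0.39, adjusted p = 0.0236), and Mfsd13a (2.12 ± 0.27, adjusted p = 0.0164). Under the same rule, the largest falls were in the protease gene Ctse (29.0 ± 6.24 against 345 ± 48.3 CPM, -3.57 ± 0.40, adjusted p = 0.0141), Atrnl1, Prr29, Ablim3, Plcb4 and Igf1r, the last with adjusted p = 0.0476, which became 0.0532 with the block. Ctse (chromosome 1, 131638306 to 131675505) and Nav1 (chromosome 1, 135434580 to 135607295) lie within 20 Mb of Ptprc, the CD45 gene whose allele marks the 2 genotypes. Camk2b, on chromosome 11, also differed between the naive genotypes of the culture part (2.21 and 3.42 CPM in wild type, 29.4 and 28.7 in deficient cells). The number of calls was 42 with an experiment term and 94 with the replicate block, the latter 39 higher and 55 lower, with 20 of them among the 22. It was 2 without any 1 of the deficient colon libraries, 8 without wild-type colon library 0, and 0 without wild-type colon library 1 or 2.

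**Figure D1:**
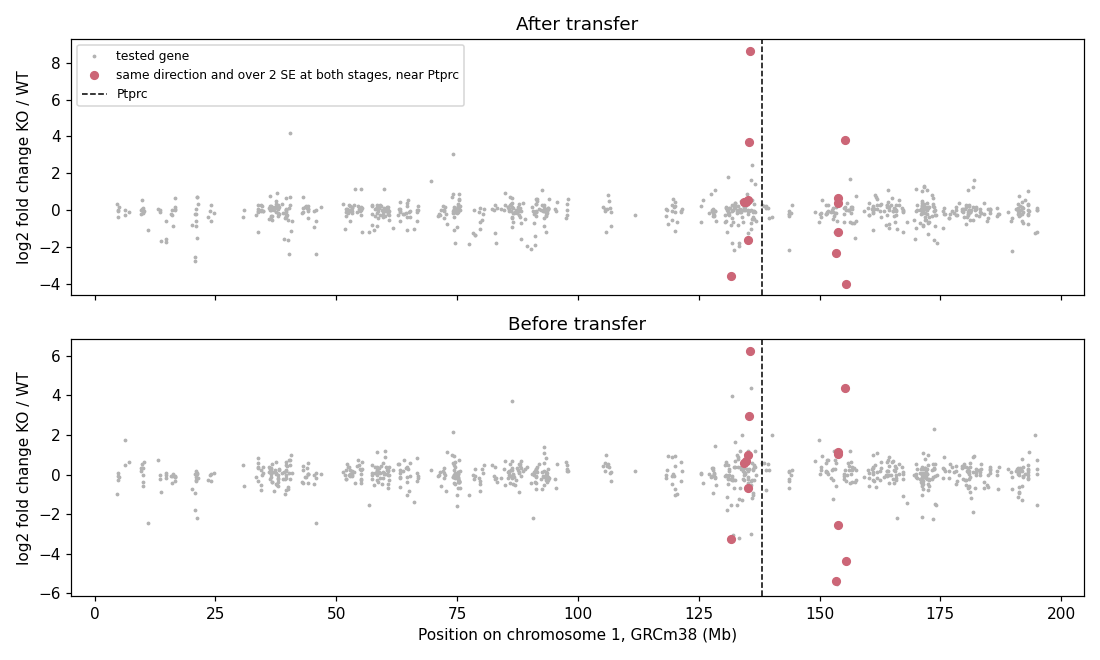
Genotype log2 fold change of each tested gene against its position in Mb on chromosome 1, after transfer (top) and before transfer (bottom), with Ptprc as a dashed line. Red points are the 13 genes within 20 Mb of Ptprc that differed in the same direction by over 2 SE at both stages.

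The Th1 list, genes of interferon-gamma producing helper cells, was higher as a set in deficient colon cells (camera adjusted p = 6.46e-08; adjusted p = 0.0751 with an estimated correlation). Of its 15 members, 5 rose and 1 fell over the list alone, or 10 and 0 with the replicate block, and Il12rb2 passed over all genes. The cytotoxic granule gene Nkg7 was at 375 ± 52.9 against 132 ± 13.2 CPM, Ifng at 378 ± 73.2 against 228 ± 61.9 and Tbx21, the gene of T-bet, at 151 ± 22 against 85.3 ± 6.94, none of which passed over all genes. Of 9 measured CD8, NK and gamma-delta T markers, 4 rose over the list alone, or 7 with the replicate block (camera adjusted p = 4.06e-06; adjusted p = 0.0751 with an estimated correlation), and Klrd1, which encodes the CD94 receptor, passed over all genes (69.1 ± 15.1 against 20.6 ± 2.44 CPM, adjusted p = 0.0181). Cd8a (48.7 ± 20.6 against 14.2 ± 2.06 CPM) and Tcrg-C4 (56.9 ± 14.3 against 14.5 ± 7.58) passed with the replicate block (adjusted p = 0.02 and 0.0125). The constant genes of the gamma chain resemble one another, so their single counts are uncertain. Itga1, an integrin chain of resident T cells, rose (155 ± 27.3 against 50.4 ± 7.15 CPM, adjusted p = 0.0164), and the homing and residency list was higher as a set (camera adjusted p = 0.00169; adjusted p = 0.0859 with an estimated correlation).

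Treg genes were higher as a set (camera adjusted p = 9.13e-06; adjusted p = 0.0751 with an estimated correlation), with 0 of 16 past the threshold over the list alone, and 9 with the replicate block. Foxp3, the regulator of regulatory T cells, was at 56.1 ± 28.7 against 22.2 ± 2.48 CPM and Ikzf2 at 91.8 ± 47.8 against 30.5 ± 4.85. The Th2 list was higher as a set (camera adjusted p = 0.0132; adjusted p = 0.0963 with an estimated correlation), with 3 of 8 genes higher and 1 lower over the list alone and Il1rl1 past the threshold over all genes. Tox2 fell (31.3 ± 0.72 against 98.2 ± 21.1 CPM, adjusted p = 0.0179) within a lower Tfh list (camera adjusted p = 0.00526; adjusted p = 0.0859 with an estimated correlation). The lists of non-pathogenic Th17, survival, interferon-stimulated and erythroid genes were higher with camera adjusted p = 0.0274, 0.0495, 0.0438 and 0.0438, and cell cycle, epithelial, stromal and endothelial, and mitochondrially encoded genes lower with 0.0438, 0.0266, 0.0438 and 0.00159. With an estimated correlation their adjusted p was 0.444, 0.465, 0.475 and 0.425 for the former and 0.875, 0.628, 0.628 and 0.444 for the latter. The non-pathogenic Th17 list had a median log2 fold change of 0.33 and a mean of -0.02, so its summaries differ in sign. The mitochondrial share of counts was 4.28% in wild-type colon library 2, against 2.27% and 2.16% in the other two. With the replicate block 7 of 12 epithelial genes fell over the list alone, and in the Tfh list 4 fell and 1 rose. Epithelial Krt19 was at 29.3 ± 19.2 against 67.4 ± 59.4 CPM. The other 13 lists did not pass as sets: pathogenic Th17, IL-6/STAT3 targets, IL-6 family receptors and sheddases, naive and central memory, inhibitory receptors and exhaustion, cell death, glycolysis, oxidative phosphorylation, cholesterol synthesis, stimulation-induced, unfolded protein and stress response, B cell and myeloid genes. Members of some moved all the same. With the replicate block 3 pathogenic Th17 genes fell over all genes, and over the list alone 6 rose and 4 fell. Entpd1 and Ighm rose and Asns fell with the block (edgeR adjusted p = 0.0348, 0.0348 and 0.0202), where without it none of these 3 passed over all genes. The STAT3-induced genes Socs3 (146 ± 34.2 against 140 ± 30.7 CPM) and Bcl3 (73.4 ± 10.2 against 87.7 ± 18.6) were among those that did not pass.

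**Figure D2:**
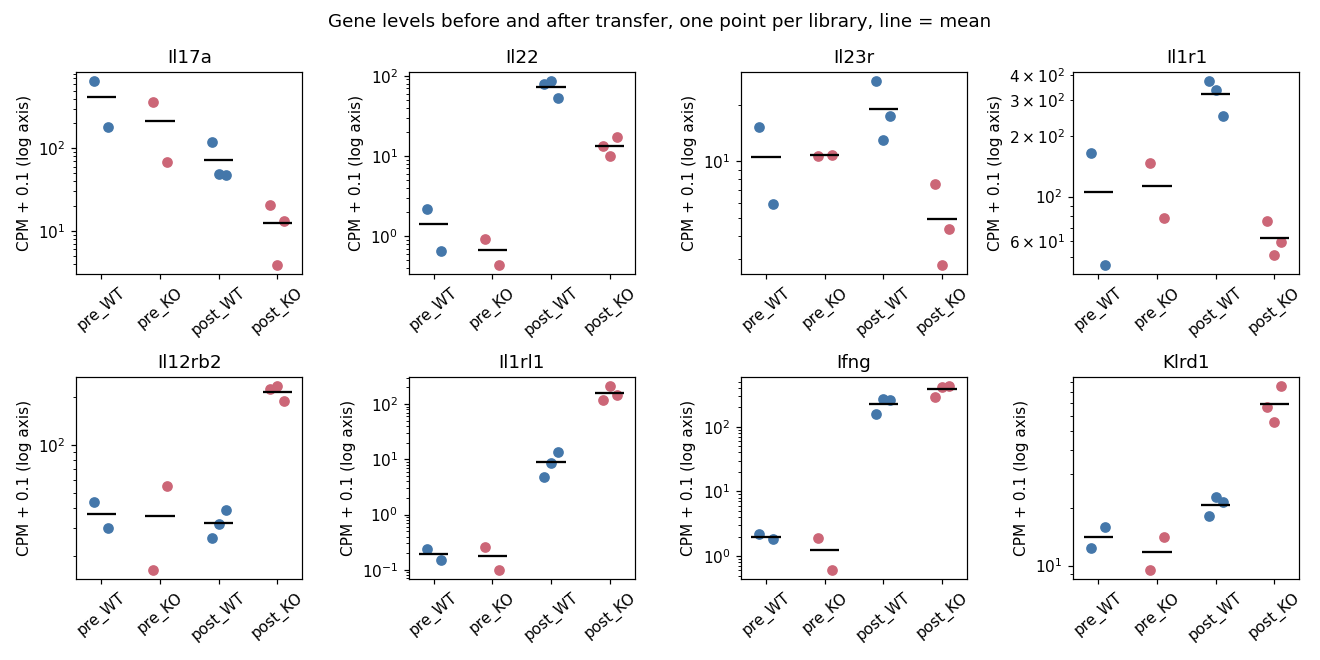
TMM-normalised CPM plus 0.1 on a log axis for 8 genes in the libraries before and after transfer, 1 point per library, with a line at the mean of each group. After transfer, Il22 averaged 72.6 CPM in wild-type and 13.3 CPM in Il6ra-deficient cells, while Il12rb2 averaged 32.1 and 215 CPM.

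Before transfer, hyper-IL-6 cultured Th17 cells without Il6ra had lower mean levels of the IL-17 cytokine genes than wild-type cells, differences that did not pass over all genes. Il23r was at 10.6 ± 0.14 CPM in Il6ra-deficient and 10.5 ± 6.63 in wild-type cells (n = 2), Il21 at 498 ± 186 and 542 ± 350, and Socs3 at 394 ± 248 and 376 ± 285. Il17a was at 214 ± 207 and 415 ± 334 CPM and Il17f at 159 ± 125 and 552 ± 479. With the replicate block their log2 fold changes were -1.12 ± 0.36 and -1.72 ± 0.21 (edgeR adjusted p = 0.792 and 0.0751), and 1 Th17 programme gene fell over the list alone. Eps8l1 was the 1 gene that passed edgeR's test (21.4 ± 1.90 against 2.31 ± 1.01 CPM, log2 fold change 3.21 ± 0.36, adjusted p = 0.0342), and 345 genes had an unadjusted p under 0.05. With the replicate block 5 genes passed, Eps8l1, Ctse, Rgs16, Camk2b and Lad1, of which the last 4 were named after their values were seen. DESeq2 called 26. As sets, oxidative phosphorylation (camera adjusted p = 0.000229), glycolysis (0.00188) and pathogenic Th17 genes (0.012) were lower in deficient cells, and with an estimated correlation the adjusted p was 0.792, 0.792 and 0.537. Wild-type library 1 stood apart, with 3.20% of counts in ribosomal protein genes against 1.20% in wild-type library 0. The count of calls was 1152 without wild-type library 0, 2 without wild-type library 1 and 0 without either deficient library. Simulated 2-fold changes were recovered in 9% of genes, so most differences of that size would have been missed.

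In the colon, wild-type cells took on Th1, interferon-response and tissue-homing genes and lost glycolytic and sterol-synthesis genes relative to the cells before transfer. Of 14225 genes, 4682 passed, 2433 higher and 2249 lower. Of 15 Th1 genes 13 rose (camera adjusted p = 6.64e-09; adjusted p = 0.0499 with an estimated correlation), with Ifng going from 1.90 ± 0.23 to 228 ± 61.9 CPM, Tbx21 from 3.43 ± 2.26 to 85.3 ± 6.94, and the chemokine receptor genes Cxcr3 from 1.25 ± 1.1 to 165 ± 16.8 and Cxcr6 from 27.1 ± 6.47 to 505 ± 93.4. Among interferon-stimulated genes 20 of 24 rose (camera adjusted p = 1.83e-10; 0.0499 as adjusted p with an estimated correlation), Irf1 from 85.5 ± 9.78 to 325 ± 22.6 CPM and Gbp7 from 30.5 ± 7.98 to 226 ± 43.5. In the homing and residency list 9 of 15 rose, Itga1 and the gut-homing receptor gene Ccr9 among them (camera adjusted p = 4.35e-06; adjusted p = 0.0499 with an estimated correlation). Glycolysis genes fell in 18 of 20 (camera adjusted p = 7.5e-11; adjusted p = 0.0499 with an estimated correlation), such as the lactate transporter gene Slc16a3 from 506 ± 7.42 to 16.6 ± 5.01 CPM and Tpi1 from 1510 ± 29.4 to 91.6 ± 15.4. Cholesterol synthesis genes fell in 18 of 21, such as Fdps from 109 ± 15.5 to 17.1 ± 4.83 CPM, and cell cycle genes in 16 of 27, such as Aurkb from 98.8 ± 0.09 to 29.2 ± 4.68. These last 2 lists passed camera with adjusted p = 6.63e-08 and 4.35e-05, with adjusted p = 0.243 and 0.551 under an estimated correlation. With the replicate block as well as an estimated correlation, 0 lists passed in this comparison. Here the block tied libraries by number across stages. Deviations of same-numbered wild-type libraries correlated across stages at only -0.143 and 0.0793, so these values give that pairing no backing.

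Th17 cytokine genes moved apart in wild-type cells after transfer. Il17a fell by 2.53 and Il17f fell by 5.71 on the log2 scale (edgeR adjusted p = 0.0323 and 0.000275), while Il22 rose from 1.31 ± 1.08 to 72.6 ± 17.3 CPM (adjusted p = 6.26e-05) and Csf2, the gene of GM-CSF, from 5.14 ± 2.89 to 26.9 ± 10.5 (adjusted p = 0.00516). Il21 fell from 542 ± 350 to 29.4 ± 3.66 CPM and Il6ra from 78.5 ± 8.05 to 6.80 ± 3.41 (adjusted p = 3.77e-05 and 0.000102). IL-6/STAT3 target genes fell in 8 of 14, with Socs3 from 376 ± 285 to 140 ± 30.7 CPM (adjusted p = 0.0433). Naive and central memory genes fell in 8 of 13, with the lymph node homing receptor gene Ccr7 from 367 ± 219 to 8.18 ± 0.17 CPM. Among the largest changes by the fixed rule, Clca4b, Ccl1, Mgat4c, Oit1 and Clca1 had no count before transfer and averaged between 12.0 and 23.9 CPM after, Gzmk averaged 53.2 ± 20.0 CPM after, and Cacnb2, Gipr and Gap43 had no count after transfer and 23.4, 13.4 and 11.7 CPM before. Markers of other colon cells rose in 15 of 16 myeloid, 8 of 12 epithelial, 6 of 10 stromal and endothelial and 5 of 5 erythroid genes, with epithelial Cdh1 at 42.1 ± 17.1 CPM and the macrophage gene C1qb at 10.5 ± 5.63 after transfer. Genes with no count before transfer, Clca4b, Oit1 and Clca1 among them, may therefore come from such cells and not from T cells. Their source was not tested. The cells before transfer were gated on the reporter and those after were not, so the stages differ in gate as well as in place and time.

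Il6ra-deficient cells changed in 3836 genes between the same stages, 1962 higher and 1874 lower. Th1 genes rose in 14 of 15 (camera adjusted p = 4.04e-13; adjusted p = 0.0307 with an estimated correlation), with Ifng going from 1.15 ± 0.90 to 378 ± 73.2 CPM and Cxcr3 from 0.56 ± 0.24 to 186 ± 20.4. Interferon-stimulated genes rose in 20 of 24, homing genes in 10 of 15 and CD8, NK and gamma-delta T markers in 7 of 9, and glycolysis genes fell in 18 of 20, with adjusted p = 0.0383, 0.0307, 0.0425 and 0.0425 with an estimated correlation. Th2 genes rose in 6 of 8 and fell in 1 (camera adjusted p = 0.000903; adjusted p = 0.0473 with an estimated correlation). In wild-type cells, Th2 genes rose in 5 of 8 (camera adjusted p = 0.0251; adjusted p = 0.187 with an estimated correlation). There, 5 of 9 CD8, NK and gamma-delta T markers rose and 2 fell (camera adjusted p = 0.037; adjusted p = 0.243 with an estimated correlation). In deficient cells, 0 lists passed with the replicate block as well as an estimated correlation. Same-numbered deficient libraries correlated across stages at -0.0811 and -0.0813 in their deviations, so the block by number lacks backing here as well. Cholesterol synthesis genes fell in 17 of 21 and cell cycle genes in 18 of 27 (adjusted p = 0.249 and 0.476 with an estimated correlation). Il17a fell from 214 ± 207 to 12.3 ± 8.24 CPM (edgeR adjusted p = 0.0049) and Il17f from 159 ± 125 to 1.48 ± 0.93 (adjusted p = 0.000173). Il22 rose from 0.58 ± 0.34 to 13.3 ± 3.59 CPM and Csf2 from 3.11 ± 1.65 to 12.4 ± 2.96 (adjusted p = 0.000298 and 0.0132). Gzmk, Esm1, Klrg1, Krt8, Car1 and Ppp2r2c had no count before transfer and averaged 64.4, 35.8, 26.9, 24.7, 23.4 and 16.2 CPM after. Of these, Krt8 and Car1 are on the epithelial list. Myeloid markers rose in 13 of 16, epithelial in 9 of 12, stromal and endothelial in 7 of 10 and erythroid in 5 of 5, with Cdh1 at 52.7 ± 10.4 and C1qb at 9.45 ± 4.96 CPM.

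Whether the genotype difference itself changed with transfer was tested by the interaction of genotype and stage. No single gene passed edgeR's test, 377 had an unadjusted p under 0.05, and DESeq2 called 13. Without wild-type library 0 before transfer 597 passed. As sets, Th1 genes and CD8, NK and gamma-delta T markers were higher in the interaction (camera adjusted p = 6.19e-07 for both) and Th17 programme genes lower (1.05e-05). With an estimated correlation the adjusted p was 0.137, 0.103 and 0.278. Over the list alone, 5 Th1 genes, 4 CD8, NK and gamma-delta T markers and 2 Th17 programme genes passed, or 9, 5 and 9 with the replicate block. Simulated 4-fold interactions were recovered in 39% of genes. Across genes, the genotype log2 fold changes after and before transfer had a Pearson correlation of 0.109 and a Spearman correlation of -0.0441, and genes are not independent replicates.

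In the culture part, 2 cultured libraries stood against their labels in most markers of the naive genotypes. Of 14 genes that separated the naive genotypes by more than 1 log2 unit and were read in culture, a rule set after the pattern was noticed, 10 separated the library labelled WT IL-6 replicate 2 and the library labelled Il6ra-deficient replicate 1 from the other 4 cultured libraries, in the direction of the naive Il6ra-deficient cells. The pair labelled Il6ra-deficient was separated by 2. Separation here is by order alone, and Rnf157 (114 against 114 CPM at the nearest libraries) and Rell1 (9.27 against 8.17) counted with almost no gap. By more than 1 log2 unit, 7 of the 14 separated the former pair and 0 any other pair. The neurofilament gene Nefh was at 0.235 and 0.413 CPM in wild-type and 8.33 and 8.18 in deficient naive cells. In culture it was at 78.4 CPM in the library labelled WT IL-6 replicate 2 and 76.7 in that labelled Il6ra-deficient replicate 1, but 2.98 in that labelled Il6ra-deficient replicate 2 and between 2.36 and 2.48 in the other 3. The vitamin B12 carrier gene Tcn2 was at 1.17 and 1.40 CPM in that pair and 6.08 in the library labelled Il6ra-deficient replicate 2, with 33.5 and 34.9 in wild-type and 10.6 and 10.1 in deficient naive cells. Labels were kept as deposited, and each direction in the cultured comparisons is a statement about the libraries as labelled.

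**Figure D3:**
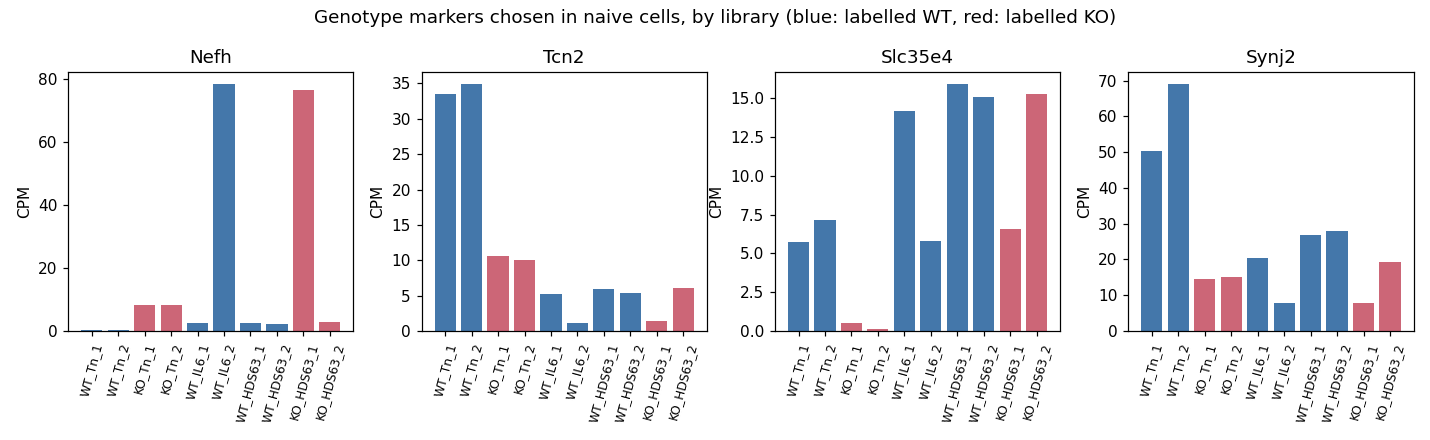
CPM of 4 genes that differ between naive genotypes, in each library of the culture part, with bars in blue for libraries labelled wild type and red for those labelled Il6ra-deficient. Nefh stands at 78.4 CPM in the library labelled WT IL-6 replicate 2 and at 2.98 CPM in that labelled Il6ra-deficient replicate 2.

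With the labels as deposited, wild-type cells cultured with hyper-IL-6 (63 ng/ml) had 1450 ± 76.6 CPM of Il17a and those labelled IL-6 (20 ng/ml) 2140 ± 500 (n = 2). Il17f was at 614 ± 37.0 against 809 ± 237 CPM, Il23r at 12.2 ± 1.32 against 20.7 ± 10.0 and Il10 at 12.0 ± 1.44 against 7.27 ± 3.49. No gene passed edgeR's test, 226 had an unadjusted p under 0.05, and DESeq2 called 5. The non-pathogenic Th17 and Treg lists were higher and glycolysis lower with hyper-IL-6 (camera adjusted p = 0.011, 0.0277 and 0.011; with an estimated correlation, adjusted p = 0.334, 0.334 and 0.544). The library labelled WT IL-6 replicate 2 is one of the libraries with crossed markers, so the 0 calls cannot be read as no difference. Without both such libraries the count was also 0, with 1 IL-6 library left.

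Cultured cells labelled Il6ra-deficient and wild type, both with hyper-IL-6, also gave no gene past edgeR's test (351 with an unadjusted p under 0.05, 3 by DESeq2). Il17a was at 2260 ± 778 against 1450 ± 76.6 CPM, Il17f at 848 ± 306 against 614 ± 37.0, Il23r at 18 ± 4.80 against 12.2 ± 1.32 and Il10 at 8.66 ± 4.78 against 12.0 ± 1.44 (n = 2). The 2 libraries labelled Il6ra-deficient differed from each other, with Il17a at 1714 and 2815 CPM and Il2 at 511 and 1113 (Il2 was named after its values were seen). Pathogenic Th17 genes were higher and non-pathogenic ones lower as sets (camera adjusted p = 0.0406 and 0.0369; with an estimated correlation, adjusted p = 0.872 and 0.572). Leaving out both libraries with crossed markers left 1 library labelled Il6ra-deficient, assumed to vary like the other groups. Then 2 genes passed, Nefh and Pik3ip1, named after their values were seen. Nefh is a marker by which those libraries were singled out, so its call is not independent of that choice. Across genes, the genotype log2 fold changes of this comparison and of the cells before transfer, from separate libraries, had a Pearson correlation of -0.0879 and a Spearman correlation of -0.289.

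Between naive CD4 T cells with and without Il6ra 1 gene passed over all genes, Pisd-ps1, a pseudogene on chromosome 11 (52.8 ± 4.86 against 10.6 ± 0.60 CPM, log2 fold change 2.31 ± 0.24, edgeR adjusted p = 0.0211), whose reads can be shared with its parent gene. Of 24 interferon-stimulated genes, 16 rose over the list alone and 0 over all genes (camera adjusted p = 1.33e-09; adjusted p = 0.44 with an estimated correlation), with Irf7 at 186 ± 17.7 against 110 ± 6.00 CPM, Oasl2 at 43.1 ± 6.86 against 15.6 ± 1.99 and Mx1 at 18.1 ± 6.59 against 4.71 ± 2.09. Of 14 IL-6/STAT3 targets, 5 fell over the list alone and 9 did not pass (camera adjusted p = 0.0331; adjusted p = 0.767 with an estimated correlation). Socs3 was at 119 ± 2.59 against 284 ± 121 CPM and Bcl3 at 31.8 ± 2.08 against 93.9 ± 72.6, where wild-type naive library 1 had 369 CPM of Socs3 and library 2 had 199. Wild-type naive library 1 also stood apart with 5.81% of counts in ribosomal protein genes, against 4.09% to 4.48% in the other 3 naive libraries. Tfh, cell cycle, glycolysis and oxidative phosphorylation genes were lower as sets (camera adjusted p = 0.00438, 1.86e-06, 0.0354 and 0.00014; with an estimated correlation, adjusted p = 0.44, 0.667, 0.681 and 0.767). DESeq2 called 95 genes. EdgeR called 902 without wild-type naive library 2, 3 without wild-type naive library 1, 0 without deficient naive library 1 and 3 without deficient naive library 2.

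Cultured cells had more mRNA of the Th17 programme than naive cells in each of the 3 labelled groups, of which those labelled IL-6 and Il6ra-deficient each hold 1 library with crossed markers. All 18 Th17 programme genes rose in wild-type cells with hyper-IL-6, in wild-type cells labelled IL-6 and in cells labelled Il6ra-deficient, with edgeR calling 10489, 10537 and 10740 of 14926 genes. The labels give stimulation with PMA and ionomycin for naive cells too, but Il2, a gene induced by it and named after its values were seen, was at 0.538 and 0.0847 CPM in wild-type and 0.103 and 0 in deficient naive cells, against 370 to 1113 after culture. Whether naive cells were stimulated is therefore unknown, and these comparisons do not separate culture from stimulation. In wild-type cells with hyper-IL-6, Il21 went from 0.886 ± 0.48 to 395 ± 18.8 CPM and Il17f from 0.0912 ± 0.01 to 614 ± 37.0, and Il17a, Ccl20, Col4a2, Gja1, Spp1 and Dlg2 had no count in naive cells and 1450, 344, 215, 141, 131 and 127 CPM after culture. All 27 cell cycle genes rose, such as Top2a from 14 ± 1.99 to 554 ± 61.9 CPM. Interferon-stimulated genes fell in 23 of 24, such as Irf7 from 110 ± 6.00 to 0.564 ± 0.02 CPM, and the interferon-inducible genes Ifi213, Ifi208, Ifi206 and Ifi214, close relatives whose reads can be shared, had 287, 213, 150 and 36.9 CPM in naive cells and no count after. Naive and central memory genes fell in 12 of 14, such as Klf2 from 958 ± 169 to 0.912 ± 0.02 CPM.

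In wild-type cells with hyper-IL-6, IL-6 family receptor and sheddase genes went both ways against naive cells, with 4 of 9 higher and 5 lower (camera adjusted p = 0.519), as did IL-6/STAT3 targets, with 6 of 14 higher and 7 lower (camera adjusted p = 0.874). Il6ra fell from 346 ± 107 to 39.5 ± 0.43 CPM, Il6st, the shared signalling chain gp130, from 588 ± 31.5 to 63.9 ± 5.04 and Socs3 from 284 ± 121 to 25.1 ± 3.29 (edgeR adjusted p = 7.89e-08, 2.45e-08 and 2.62e-07). Foxp3 fell from 21.1 ± 3.71 to 5.68 ± 0.25 CPM (adjusted p = 8.8e-05). The Th17, cell cycle, interferon-stimulated and naive lists passed camera in wild-type cells with hyper-IL-6 with adjusted p = 5.62e-07, 1.43e-09, 2.12e-08 and 5.4e-05. With an estimated correlation their adjusted p was 0.069, 0.291, 0.291 and 0.069. In cells labelled Il6ra-deficient, Il21 went from 0.182 ± 0.19 to 532 ± 74.5 CPM and Socs3 from 119 ± 2.59 to 27.9 ± 1.57, with cholesterol synthesis genes rising in 18 of 21 and oxidative phosphorylation genes in 18 of 22. In cells labelled IL-6, Il21 went to 518 ± 144 CPM and Foxp3 from 21.1 ± 3.71 to 4.52 ± 1.99. Across genes, the culture log2 fold changes of wild-type and labelled Il6ra-deficient cells with hyper-IL-6 had a Pearson correlation of 0.939. The interaction of genotype and culture gave no gene past edgeR's test, 1267 with an unadjusted p under 0.05 and 51 by DESeq2. Without wild-type naive library 2 it gave 392, and without wild-type naive library 1 it gave 1. It carried the same doubt about the library labelled Il6ra-deficient replicate 2, and without both libraries with crossed markers, which leaves 1 library in that arm, 1 gene passed, Pisd-ps1, a marker of the naive genotypes named after its values were seen.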

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

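The tests of crossed markers, of the interval near Ptprc and of natural killer cells were chosen after the results were seen, while the interaction tests were planned.

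The interaction of genotype and stage stood out because 7 lists differed between the genotype effects after and before transfer by camera: Th17 programme (adjusted p = 1.05e-05), Th1 (6.19e-07), Treg (0.000321), Th2 (0.0479), glycolysis (0.00185), oxidative phosphorylation (0.00179) and CD8, NK and gamma-delta T markers (6.19e-07). Of these, the Th17 programme was lower and the others higher. The interaction of genotype and culture stood out for 6 lists: IL-6/STAT3 targets (0.0184), Tfh (0.00201), cell cycle (3.15e-05), glycolysis (0.00366), oxidative phosphorylation (0.000155) and interferon-stimulated genes (5.5e-06). It rests in part on the library labelled Il6ra-deficient replicate 2. With an estimated correlation none of these lists passed, in either interaction. Alignments to several places were a signal outside the counts, with a ratio to unique reads of 1.34 in wild-type library 1 before transfer.

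In most of 14 markers, the 2 libraries labelled WT IL-6 replicate 2 and Il6ra-deficient hyper-IL-6 replicate 2 stood with the other naive genotype. If they had been exchanged, most markers would separate the former and Il6ra-deficient replicate 1 from the other 4 cultured libraries. Of 14, 10 did, where the most for any other of the 15 pairs was 2. Igha, named after its values were seen, did not, as it was at 0.0279 CPM in the library labelled Il6ra-deficient replicate 2 and at 0.0286 and 0.0307 in that pair. Pisd-ps1 was lower in that pair (15.1 and 13.1 CPM) than in the other libraries (18.9 to 24.3), against its naive direction. A single chromosome 11 segment inherited apart from Il6ra is argued against, since 5 of the 8 markers outside its first 10 Mb separated the same pair, 3 of them by more than 1 log2 unit (Synj2, Gm16867 and Gm47283, on chromosomes 17, 14 and Y, named after their values were seen). Several background segments that vary between mice stay open, as may an exchange of the labels, and an effect of the cytokine cannot give opposite markers in replicates of 1 group. Il6ra did not decide it, at 30.6 and 31.8 CPM in the 2 libraries.

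Of 86 genes beyond 2 SE at both stages 75 had the same sign, among them 13 of 178 tested genes within 20 Mb of Ptprc and 62 of 14047 elsewhere (odds ratio 17.8, 95% interval 8.78 to 33.4, two-sided Fisher's exact p = 7.65e-12). For the genes near Ptprc, the median signed log2 fold change of the 10 measured in the culture part was 0.0885 between naive genotypes. This cannot decide whether an effect of Il6ra is also present in naive cells. The filter ran over all culture-part groups, so these genes need not be expressed in naive cells, and Rgs16 had a value of 0. The CD45 alleles of the culture-part mice are not stated here either, so these values do not test the interval. Naive cells cannot show an effect of Il6ra that appears only in cultured or colon cells, so such an effect stays open for all of these genes. Nav1 had 1.29 between naive genotypes in the same direction as after transfer, and Ctse 0.12. A candidate explanation for the genes near Ptprc is the congenic interval that came with the CD45.1 allele, which was not tested apart from Il6ra. Other differences between the 2 lines stay open.

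CD8, NK and gamma-delta T markers were higher in Il6ra-deficient colon libraries, with Klrd1 (log2 fold change 1.74 ± 0.24) the 1 gene that passed over all genes and larger estimates for Klre1, Tcrg-C4 (1.98) and Cd8a (1.78). Natural killer cells cannot be told apart from other sources, because their genes went both ways: Klrb1c had a log2 fold change of -0.27 ± 0.36 with an upper 95% limit of 0.61, below Klrd1, while Klre1, at a low level, had 2.34 ± 0.68 and Gzma 1.12 ± 0.55. The sort was gated on CD4 and the T cell receptor beta chain, which would remove natural killer, CD8 and gamma-delta T cells but not cytotoxic CD4 T cells. Cells that escaped the gate, cytotoxic CD4 T cells and an effect of Il6ra may each have contributed and stay open, and all 10 splits of the 6 colon libraries are too few for a share under 0.05. The real split called 22 genes and the highest other split 0, with 1 of 10 splits giving as many.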

How the results depend on the processing

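Planned were all settings here except DESeq2 on the compared groups only, the compared groups only with the replicate block, the 3 cultured groups only, the fits without doubted libraries or libraries with crossed markers, and camera with a replicate block and an estimated correlation, which were chosen after seeing the data. The cause of each change below was not tested. Of the named genes under each setting, 1846 gene and setting pairs kept their status, whether called or not called. A call was lost in 110 pairs and gained in 132, and 0 changed direction with a call. Low counts, 2 or 3 libraries per group and single libraries that move the counts may limit the genotype comparisons, which was not tested. In simulated colon counts DESeq2 called 39 unchanged genes beside 125 changed ones.

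For colon genotypes (22 genes) the count was 120 with no filter on low counts, 133 with DESeq2, 108 with the compared groups only, 445 with DESeq2 on these, 42 with an experiment term, 94 with the replicate block and 247 with the compared groups only and the replicate block. With 1 library left out it lay between 0 (without wild-type colon library 1) and 8 (without wild-type colon library 0). Without both doubted libraries, wild-type library 1 before transfer and wild-type colon library 2, it was 23, but only 11 of the 22 genes were among them. Before transfer (1 gene) the count was 17 with no filter, 26 with DESeq2, 0 with the compared groups only, 12 with DESeq2 on these, 5 with the replicate block, 2 with an experiment term and 0 without both doubted libraries, and between 0 and 1152 with 1 library left out, the highest without wild-type library 0. For genotype by stage (0 genes) it was 13 with no filter, 13 with DESeq2, 1 with the replicate block, and between 0 and 597, the highest again without wild-type library 0 before transfer. The compared groups are all groups there, so that setting was not run.

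In the culture part, where numbers only name libraries, the replicate block left 0 genes for naive genotypes (1 gene) and changed the counts of the other comparisons by less than 1.5 times. Same-numbered libraries correlated at between -0.164 and 0.156 in their deviations. Hyper-IL-6 against IL-6 (0 genes) gave 36 with no filter, 5 with DESeq2 and 25 with DESeq2 on the compared groups. The labelled genotypes with hyper-IL-6 (0 genes) gave 74, 3 and 21 in these settings, 2 without both libraries with crossed markers, and between 0 and 1 with 1 library left out. Naive genotypes gave 439 with no filter, 95 with DESeq2, 5 with the compared groups only, 69 with DESeq2 on these, and between 0 and 902 with 1 library left out, the highest without wild-type naive library 2. Genotype by culture (0 genes) gave 271 with no filter, 51 with DESeq2, 30 with DESeq2 on the compared groups, 1 without both libraries with crossed markers, and between 0 and 392 with 1 library left out. With a 2-fold minimum, culture with hyper-IL-6 called 6952 and with IL-6 6970 genes against naive cells.

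The number of lists called fell to 0 with an estimated correlation in every comparison except wild-type colon against before transfer (4) and deficient colon against before transfer (6), and to 0 in all with the replicate block and an estimated correlation. With fry, 5 lists passed for colon genotypes: Th1, Treg, Th2, Tfh, and CD8, NK and gamma-delta T markers. The Th17 programme was not among them. Fry passed 3 lists for genotype by stage, 1 for genotype by culture, 24 for either wild-type culture against naive cells and 25 for the culture labelled deficient. It passed 0 before transfer, for the 2 cultured comparisons and for naive genotypes. Camera with the replicate block called 8 lists before transfer and 0 for the labelled genotypes with hyper-IL-6, where RLE size factors called 1.

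The correlation of genotype effects after and before transfer was -0.0441 by rank, 0.0296 over genes with mean log2 CPM of at least 4, and between -0.0198 and 0.156 with 1 library left out. The correlation of the effect before transfer with that of the labelled cultures was -0.289 by rank, -0.238 over such genes, and between -0.15 and 0.0062 with 1 library left out, the highest without the library labelled Il6ra-deficient replicate 2. The correlation of the 2 culture effects was 0.985 over such genes and between 0.894 and 0.932 with 1 library left out.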

Other observations

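In the colon, stimulation-induced genes went both ways against the cells before transfer, with 5 of 15 higher and 3 lower in wild-type cells and 6 higher and 3 lower in deficient cells (camera adjusted p = 0.631 and 0.522). Of 15 stress response genes, 4 rose and 2 fell in wild-type cells and 4 rose and 4 fell in deficient cells (camera adjusted p = 0.781 and 0.752). In wild-type cells Fos rose from 43.2 ± 11.9 to 678 ± 137 CPM and Fosb from 10.9 ± 0.26 to 831 ± 340, the immediate-early genes of the AP-1 factor, and the heat shock gene Hspa1b from 3.78 ± 0.16 to 101 ± 36.9, while Lif fell from 935 ± 572 to 16.3 ± 3.41 and Tnfrsf9 from 318 ± 46.8 to 45.5 ± 10.9. Hspa1b shares reads with its near-identical copy Hspa1a. The inhibitory receptor gene Lag3 fell from 1120 ± 410 to 42.0 ± 13.7 CPM, whereas Havcr2, the gene of TIM-3, rose from 0.293 ± 0.22 to 50.5 ± 20.0. In deficient cells Fos rose to 699 ± 154 and Fosb to 888 ± 441 CPM, and Lag3 fell from 586 ± 22.4 to 43.4 ± 7.65.

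Culture also changed genes of the metabolic and survival lists. In wild-type cells with hyper-IL-6, the hexokinase gene Hk2 rose from 0.824 ± 0.15 to 252 ± 9.01 CPM and Tpi1 from 29.6 ± 2.85 to 559 ± 30.5, whereas Pdk1 fell from 591 ± 16 to 56.3 ± 3.31. The anti-apoptotic gene Bcl2l1 rose from 19.0 ± 4.80 to 248 ± 20.4 CPM and the IL-7 receptor gene Il7r fell from 666 ± 6.42 to 69.3 ± 0.00. The sterol genes Sqle and Cyp51 rose from 31.3 ± 4.13 to 179 ± 2.09 and from 31.4 ± 6.75 to 227 ± 0.93 CPM. Whether naive cells were stimulated like the cultured ones is unknown.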
